A study of Mus musculus with 9 samples.

How the data were processed

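RNA was measured in WT-1 cells, a mouse line of brown preadipocytes that had been differentiated into adipocytes. Per the labels, lentivirus with a non-targeting shRNA or an shRNA against H2A.Z was added on day 6, and vehicle or CL316,243, an agonist of the β3-adrenergic receptor, was given for 4 h on day 11. Total RNA was depleted of rRNA, and libraries were made with the CORALL RNA-Seq V2 kit. The 9 libraries form 3 groups of 3, which are control cells with vehicle, control cells with CL316,243, and knockdown cells with CL316,243. A vehicle-treated knockdown group is not analysed here, so an interaction of knockdown and stimulation was not tested. The labels do not say whether the replicates came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical.

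The deposited matrix holds whole-number counts for 55228 gene symbols in the 9 libraries, aligned to mm10. The authors' notes name Trim Galore 0.6.6, STAR 2.7.9a, deepTools 3.3.1 and DESeq2 1.32.0. The counting program, the annotation release, the strand setting and the handling of molecular identifiers are not given in the sources used here. The authors also deposited a DESeq2 table for each of the comparisons of stimulated with vehicle control and of stimulated knockdown with stimulated control. In these deposited tables the fold changes and their standard errors are log2 values. The p-values in the deposited tables are raw and adjusted p-values. The deposited test statistic is a score, the Wald statistic of DESeq2. The other deposited column of these tables is the mean of size-factor normalised counts over the libraries compared. These tables list 13045 and 11838 genes, named as protein-coding in the deposit, and the rule by which genes were kept in them is not given in the sources used here. A DESeq2 fit of the 6 libraries compared with a term for the replicate number gave the deposited fold changes and standard errors of all 13045 and 11838 genes again, and a fit without that term did so for at most 2. The authors' tables thus treat equal numbers as pairs in both comparisons, which was found after the analysis without a block had been fixed.

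Gene positions and types came from GENCODE M21 on mm10, in which 53456 symbols matched 1 gene record, 113 matched several and 1659 matched none. Total counts ran from 12906922 to 17077453 per library. Without known handling of molecular identifiers, reads may include copies of one molecule. No pair of libraries of a group was alike within counting noise, the lowest chi-square per degree of freedom between such a pair being 3.63 over genes with at least 20 counts.

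Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr on the 3 groups, which left 29018 genes, and a quasi-likelihood fit of all 9 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes are from this fit unless another tool is named. CPM values are given as mean ± SD over 3 libraries, and log2 fold changes with their SE. The fit had 6 residual and 35.1 prior degrees of freedom. The comparisons were stimulated control minus vehicle control, stimulated knockdown minus stimulated control, and stimulated knockdown minus vehicle control.

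The 24 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. Each list was tested again with an estimated correlation and with fry, both without a replicate block. A list needed at least 4 measured members. Some genes stand in more than 1 list, among them Acsl1, Angptl4 and Per1. The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change, at a mean CPM of at least 2, with the 3 libraries of one group above the 3 of the other, and without predicted or clone names. H2afz, H2afv, Ucp1, Ppargc1a, Dio2, Nr4a1, Pparg, Adipoq, Fgf21 and Fasn were always named, as were up to 4 called members of each list with the largest changes. Other list members in the text were chosen as examples after their values were seen.

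Whether equal replicate numbers pair the libraries was checked by the correlation, over genes, of each library's deviations from its group mean. The labels give the same replicate numbers in each group but do not say that a number marks a shared culture or day, so the pairing rests on these values. Between stimulated and vehicle control the same-number correlations were 0.19, 0.50 and 0.24, each over the limit set in advance, and values from a fit with a replicate block are given beside that comparison (2632 genes higher and 3013 lower). Stimulated control library 1 correlated as highly with vehicle library 3 (0.19) as with vehicle library 1. The prior degrees of freedom of the blocked fit came out infinite, so that every gene took its spread from the trend, while 20 genes were spread beyond that trend. Its counts are therefore given without p-values for single genes.

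The fit without a block was tested on simulated data of unpaired libraries, drawn at the dispersion of that fit. Of genes changed 1.5-, 2- and 4-fold, 41.8%, 82.1% and 100% were called in the comparison of stimulated with vehicle control, with 5 of 155 calls on unchanged genes. For knockdown against stimulated control these shares were 47.8%, 82.1% and 98.5%, with 6 of 162 calls on unchanged genes. A list raised as a whole was called in both comparisons, and 0 other lists were. Genes were drawn independently here, so this does not show how often correlated genes give a false list call. In the real data the estimated correlation reached 0.836, for the interferon list in the knockdown. In a further simulation with 1 member of each list lowered 4-fold, 19 of the 24 lists were called, so a call by camera with the preset correlation can come from 1 gene.

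Comparisons that share the stimulated control libraries were set against 50 simulated data sets with the fitted CL316,243 effect and no knockdown effect, and 50 with neither effect. These draw unpaired libraries at the gene-wise dispersions of the fit without a block, whose common value was 0.0165, against 0.00441 in the fit with a replicate block. A further 50 with the fitted CL316,243 effect alone, chosen after seeing the data, were drawn from the fit with the block and analysed without it. All draw genes independently, so a value beyond every draw excludes nothing. The alternatives were DESeq2 size factors, upper-quartile factors, library totals, no filter, a CPM of at least 1 in 3 libraries, the replicate block, the DESeq2 1.42.0 Wald test without a replicate term, only genes in the deposited tables, only the 6 libraries compared, no mitochondrially encoded genes, an adjusted p under 0.01, and each library left out. Alternatives without the 3 libraries numbered 2, and with the block under a robust prior or in DESeq2, were chosen after seeing the data.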

Results

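Gene expression was measured by RNA sequencing of rRNA-depleted total RNA in WT-1 brown adipocytes, in 3 groups of 3 libraries. The groups were control cells with a non-targeting shRNA and vehicle, control cells with CL316,243, and H2A.Z knockdown cells with CL316,243. H2A.Z is a histone variant encoded in the mouse by H2afz and H2afv. Total counts were 15129254, 12929562 and 17077453 in the vehicle control libraries 1 to 3. They were 16733090, 13170255 and 15307546 in the stimulated control and 13501703, 12906922 and 15318483 in the stimulated knockdown. Mitochondrially encoded genes took 11.3% to 14.45% of the counts of a library. The first principal component held 28.3% of the variance, and the library numbered 2 had the lowest value on it in each of the 3 groups. On the second component, with 22.8%, the 3 vehicle libraries lay at 16.8 to 57.2 and the 6 stimulated libraries at -30.5 to 0.1.

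**Figure D1:**
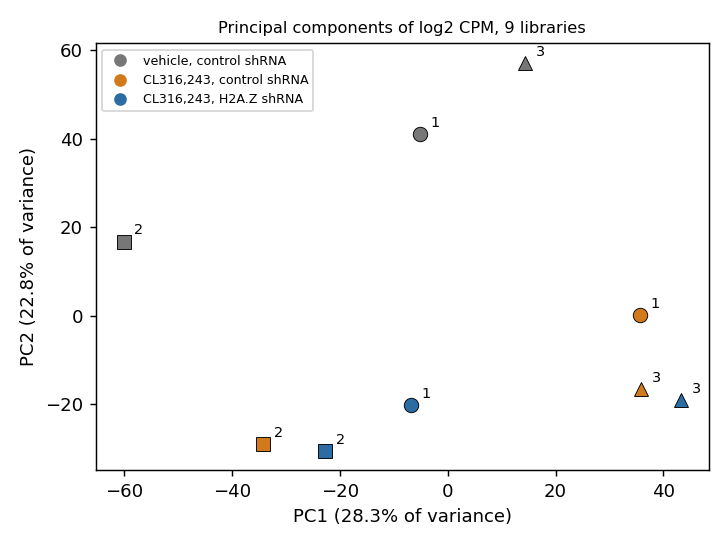
First and second principal components of log2 CPM in the 9 libraries, in units of the component scores, with the replicate number beside each point and the group given by colour. The 3 vehicle libraries lie at 16.8 or above on the second component, and the libraries numbered 2 lie at -60.1, -34.2 and -22.8 on the first.

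The first question was whether H2A.Z RNA was lower in the knockdown, and for which gene. H2afz (ENSMUSG00000037894.13, mm10 chromosome 3, 137864487 to 137866922) was 84.87 ± 10.8 CPM in the stimulated control and 40.14 ± 6.3 CPM in the stimulated knockdown (SD, n = 3). Its log2 fold change was -1.08 with an SE of 0.135 and an adjusted p of 1.57e-06, and the 3 knockdown libraries, at 46.73, 34.18 and 39.52 CPM, lay below all 3 stimulated control libraries. H2afv (ENSMUSG00000041126.16, chromosome 11, 6427229 to 6444443) was 32.82 ± 3.92 CPM in the stimulated control and 34.52 ± 1.53 CPM in the knockdown, a log2 fold change of 0.07 with an SE of 0.139 and an adjusted p of 1. With CL316,243 in control cells H2afv fell from 52.54 ± 12 CPM, with a log2 fold change of -0.68, an SE of 0.137 and an adjusted p of 4.41e-04. H2afz was 102.3 ± 11 CPM with vehicle, and its log2 fold change with CL316,243 was -0.27 with an SE of 0.13 and an adjusted p of 0.248. This last change was called when library totals replaced TMM (-0.37) and in the fits with a replicate block (-0.27 in edgeR). H2afz is also called lower with CL316,243 in the authors' deposited table, which has a replicate term (-0.22, adjusted p 0.0355). The labels do not say which of the H2A.Z genes the shRNA targets.

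**Figure D2:**
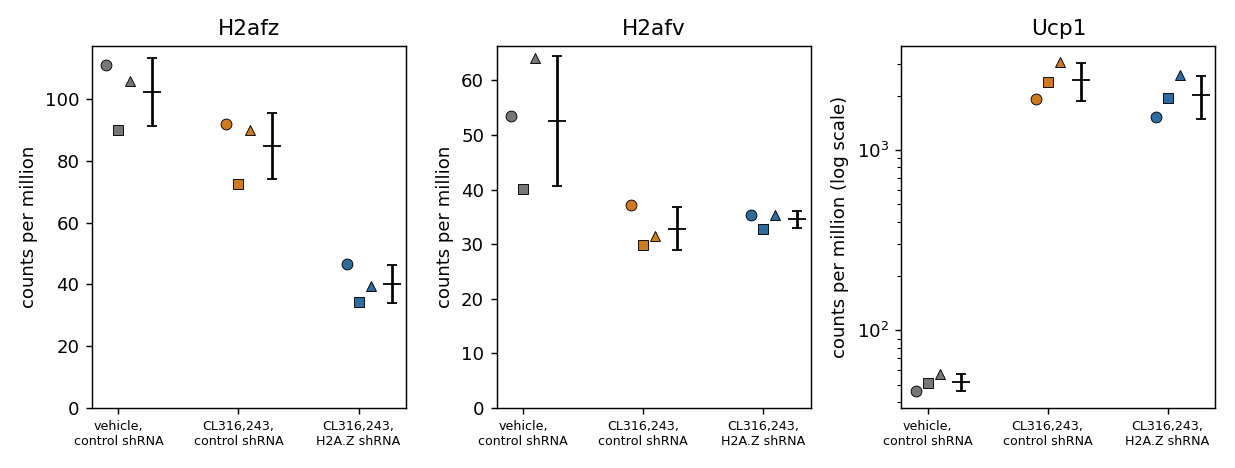
CPM of H2afz, H2afv and Ucp1 in each library, with circles, squares and triangles for replicates 1, 2 and 3, and bars for the mean ± SD of the 3 libraries of a group. The Ucp1 axis is logarithmic. H2afz averaged 40.14 CPM in the knockdown against 84.87 CPM in the stimulated control, and Ucp1 rose from 51.53 CPM with vehicle to 2447 CPM with CL316,243.

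The comparison of stimulated with vehicle control asked which genes respond to 4 h of β3-adrenergic stimulation. Ucp1, the uncoupling protein of brown fat mitochondria (ENSMUSG00000031710.4, chromosome 8, 83290352 to 83298452), rose 47.5-fold, from 51.53 ± 5.65 to 2447 ± 575 CPM (SD, n = 3; log2 fold change 5.57, SE 0.214, adjusted p 1.05e-22). The orphan nuclear receptor genes Nr4a3 and Nr4a1 rose 22.4-fold and 9.26-fold. Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, rose 12-fold, and the free fatty acid receptor gene Ffar4 rose 9.09-fold. Ak4, Sema3g, Gprc5a, Ero1l and Smim41 completed the 10 largest rises, at log2 fold changes of 3.31, 3.25, 3.17, 3.09 and 3.31. Among the 10 largest falls were Angpt1, which encodes angiopoietin 1 (log2 fold change -1.92), the β3-adrenergic receptor gene Adrb3 (-1.82) and the leptin gene Lep (-1.78). The others were Strip2 (-1.84), Gprin3 (-1.65), Gbp6 (-1.62), Lfng (-1.58), Foxo6 (-1.55), Coq8a (-1.53) and Chdh (-1.51).

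Of 29018 genes tested, 1401 were higher and 1413 lower with CL316,243, of which 416 and 123 changed at least 2-fold. An unadjusted p under 0.05 was reached by 5469 genes, and the groups did not overlap for 6123 genes, where chance gives 10% of genes in unpaired libraries. The fit with a replicate block called 2632 genes higher and 3013 lower. The share of calls that were higher depended on the scaling, at 49.8% with TMM, 60.8% with DESeq2 size factors, 65.6% with upper-quartile factors and 32.7% with library totals. The DESeq2 Wald test called 669 genes lower, and the lower calls ran from 683 without vehicle library 3 to 1938 without vehicle library 2, while the higher calls fell to 907 without stimulated control library 3. Calls at least 2-fold lower ran from 77 without vehicle library 3 to 176 without stimulated control library 1, and were 73 with only the genes of the deposited tables, which gave 237 at least 2-fold higher, 81 with upper-quartile factors and 187 with library totals. They were 81 with the replicate block in DESeq2. The authors' deposited table calls 2267 genes higher and 1340 lower, and the 2192 genes called in both had the same sign.

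Early response genes of cAMP signalling rose as a group, with 24 of 29 measured members higher and 1 lower (24 and 1 adjusted over the list alone; camera adjusted p 1.11e-59, adjusted p = 0.0243 with an estimated correlation). Besides Nr4a3 and Nr4a1, the phosphodiesterase gene Pde4d (log2 fold change 2.79) and the salt-inducible kinase gene Sik1 (2.52) rose, and Rgs2, a regulator of G protein signalling, fell (-1.20). Genes of glucose uptake and glycolysis rose, with 17 of 20 members higher and 0 lower by edgeR, where 1 was lower at an unadjusted p under 0.05 and 0 in DESeq2 (17 and 1 adjusted over the list alone; camera adjusted p 7.09e-76, adjusted p = 0.017 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 47.8 ± 7.65 to 319.1 ± 92 CPM, and Hk2, which encodes hexokinase 2, from 76.32 ± 16.1 to 263.7 ± 28.2 CPM (SD, n = 3). The monocarboxylate transporter gene Slc16a3 rose by a log2 fold change of 2.52 and the phosphofructokinase gene Pfkp by 2.07.

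Of the 28 genes of the thermogenic programme, 10 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p 1.43e-10, adjusted p = 0.0115 with an estimated correlation). The fatty acid elongase gene Elovl3 rose by a log2 fold change of 2.22, the glycerol kinase gene Gk by 1.99 and the coactivator gene Ppargc1a by 1.17, while Adrb3 and P2rx5 fell. Dio2, the thyroxine-activating deiodinase gene, was 1.57 ± 0.62 CPM with vehicle and 3.03 ± 1.08 CPM with CL316,243 (log2 fold change 0.95, adjusted p 0.0441). The Dio2 call was lost in the DESeq2 Wald test (1.01), without the 3 libraries numbered 2 (1.14), with upper-quartile factors (1), library totals (0.83), a CPM of at least 1 in 3 libraries (0.94), only the genes of the deposited tables (0.96) or only the 6 libraries compared (0.92). It was also lost without vehicle library 1 (1.06) or 3 (0.67) and without stimulated control library 2 (0.89) or 3 (0.70). The authors' deposited table does not call Dio2 (0.995, adjusted p 0.102). Fgf21, a hormone of brown fat, had 2 to 15 raw counts per library and was removed by the filter on low counts.

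**Figure D3:**
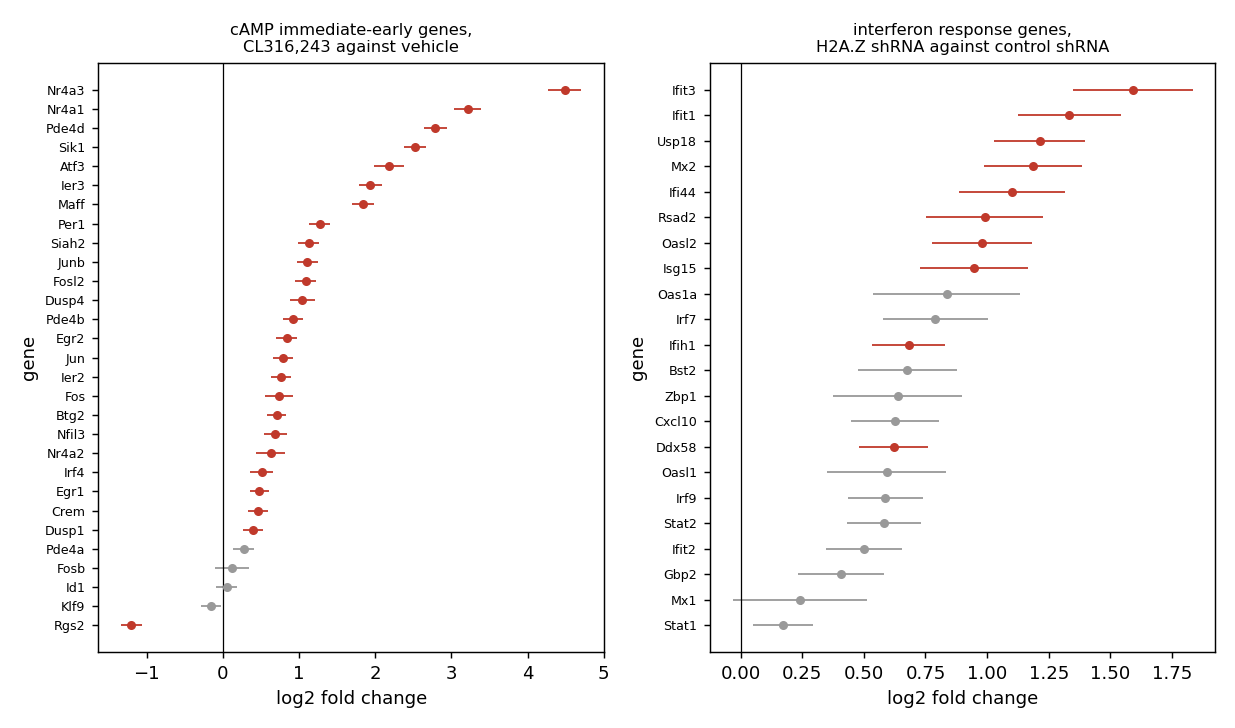
Log2 fold change ± SE of the 29 measured cAMP early response genes in stimulated against vehicle control, and of the 22 interferon-response genes in stimulated knockdown against stimulated control, from edgeR on 3 libraries per group. Red marks an adjusted p under 0.05 and grey the rest, with 25 red points in the first list and 10 in the second.

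Lipid genes moved in both directions. In lipolysis and lipid droplet genes 8 of 17 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p 2.26e-07, adjusted p = 0.399 with an estimated correlation), led by Hilpda (2.52), an inhibitor of the triglyceride lipase, and the droplet coat gene Plin2 (1.87). In fatty acid uptake and oxidation 8 of 23 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p 2.03e-05, adjusted p = 0.678 with an estimated correlation), among them the acyl-CoA synthetase gene Acsl1 (1.31) and the peroxisomal oxidase gene Acox1 (1.03). Of 18 genes of fatty acid and triglyceride synthesis 5 rose and 5 fell, adjusted over all genes or adjusted over the list alone, and the list was not called (adjusted p 0.516). The acyltransferase gene Dgat1 rose (1.56) and Lpin1 rose (0.86), while Thrsp (-0.93), Mlxipl (-0.85) and the fatty acid synthase gene Fasn (-0.54) fell. The Fasn call, at an adjusted p of 0.0424, was lost in the DESeq2 Wald test (-0.49), with DESeq2 size factors (-0.49) or upper-quartile factors (-0.47), without a filter (-0.52), with only the genes of the deposited tables (-0.52) and without the 3 libraries numbered 2 (-0.54). It was also lost without vehicle library 1 (-0.33), stimulated control library 2 (-0.48) or 3 (-0.38), or knockdown library 2 (-0.52), while the authors' deposited table calls Fasn lower with CL316,243 (-0.50, adjusted p 7.31e-14). The synthesis list was called upward without vehicle library 1 (mean against all genes 0.224). In sterol synthesis and uptake 5 of 19 genes rose (6 rose and 2 fell adjusted over the list alone; camera adjusted p 1.78e-04, adjusted p = 0.679 with an estimated correlation), among them Sqle (1.24) and Hmgcr (0.85), which encode rate-limiting enzymes of the pathway.

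In the unfolded protein and integrated stress response 11 of 18 genes rose and 1 fell (12 and 3 adjusted over the list alone; camera adjusted p 1.83e-11, adjusted p = 0.24 with an estimated correlation), with Ddit4 at a log2 fold change of 2.7, Trib3 at 1.03 and Ppp1r15a at 1.01. Among secreted factors 7 of 19 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p 0.0015, adjusted p = 0.0595 with an estimated correlation), including Il6 (1.71), the angiogenic factor gene Vegfa (1.23) and Nrg4 (0.93). Of 25 nuclear-encoded oxidative phosphorylation genes 2 rose, Cycs (0.90) and Uqcrfs1 (0.46), the same number as adjusted over the list alone (camera adjusted p 0.00125, adjusted p = 0.83 with an estimated correlation), and the authors' deposited table calls 13 higher. That list was not called without vehicle library 2 (mean against all genes 0.051), nor was Uqcrfs1 without vehicle library 2 (0.36), stimulated control library 1 (0.40) or 3 (0.43), or knockdown library 1 (0.43). Uqcrfs1 was also not called without a filter (0.49). Of 18 proliferation genes 7 fell, among them Cdc20 (-0.67), Mki67 (-0.55) and Plk1 (-0.52), with 10 lower adjusted over the list alone (camera adjusted p 1.62e-04, adjusted p = 0.679 with an estimated correlation). The DESeq2 Wald test called 3 of them, Mki67, Ccnb1 and Cdc20, and without vehicle library 3 Mki67 (-0.41) and Plk1 (-0.33) were not called. With DESeq2 size factors in edgeR Mki67 was not called either (-0.50).

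Clock genes changed in both directions, with 7 of 16 higher and 4 lower (8 and 5 adjusted over the list alone), and the list was not called (adjusted p 0.143). Bhlhe40 (1.48) and Per1 (1.27) rose, while Per3 (-1.40) fell. Of 18 genes of H2A.Z deposition and removal 2 rose, Ruvbl2 (1.22) and Actr6 (0.64), the same number as adjusted over the list alone (adjusted p 0.357). Of 17 adipocyte identity genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p 0.394), and Pparg and Adipoq had log2 fold changes of -0.07 and -0.06, which turned to 0.01 and 0.02 with upper-quartile factors. Of 16 p53 targets 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p 0.987), with Cdkn1a at 1.08 and Trp53inp1 at -0.996. Among chromatin looping factors Pds5b fell (-0.39, adjusted p 0.0494; list adjusted p 0.762), among other histone variants Cenpa fell (-0.53; list adjusted p 0.529), and among nuclear-retained RNA Kcnq1ot1 rose (0.73; list adjusted p 0.309). Cd44 (0.39, adjusted p 0.0425) was the 1 called gene among 19 preadipocyte and fibroblast markers (list adjusted p 0.762). Pds5b and Cd44 were not called adjusted over the list alone or in DESeq2, whereas Cenpa and Kcnq1ot1 were called adjusted over the list alone. Cd44 was not called with any 1 library left out (0.31 to 0.46), Pds5b in 7 of these 9 fits (-0.46 to -0.31), and Cenpa without vehicle library 3 (-0.33) and in DESeq2. The authors' deposited table calls Cd44 (0.44, adjusted p 0.00148), Pds5b (-0.33, adjusted p 3.85e-05) and Cenpa (-0.46, adjusted p 4.46e-05). Clock genes were called upward without vehicle library 1 (mean against all genes 0.23) or stimulated control library 2 (0.314), and H2A.Z deposition genes without vehicle library 3 (0.208).

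Interferon-response genes (adjusted p 0.621) and mitochondrially encoded mRNA (0.987) were not called with CL316,243, nor were macrophage (0.714), endothelial (0.637) and skeletal muscle markers (0.987). In these lists edgeR called 0 members adjusted over all genes or adjusted over the list alone, and DESeq2 without a replicate term called 0. The authors' deposited table calls 2 of 19 interferon genes lower, and 2 of 7 mitochondrially encoded genes higher and 3 lower. At an unadjusted p under 0.05, 3 interferon genes and 1 endothelial marker were lower, and without vehicle library 1 the interferon list was called downward (mean against all genes -0.222). Median, mean and test differed in sign for mitochondrially encoded mRNA (median -0.03, mean 0.12, test downward), the fibroblast markers (median 0.03, mean -0.004, test upward) and nuclear-retained RNA (median -0.04, mean 0.09, test upward).

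The comparison of stimulated knockdown with stimulated control asked which genes differ when H2A.Z is lowered during stimulation. The carboxylesterase gene Ces2e (ENSMUSG00000031886.14, chromosome 8, 104926260 to 104934672) rose 4.34-fold, from 2.55 ± 1.13 to 11 ± 3.15 CPM (SD, n = 3; log2 fold change 2.12, SE 0.24, adjusted p 2.09e-07). Il1rn, which encodes the interleukin 1 receptor antagonist (ENSMUSG00000026981.15, chromosome 2, 24336853 to 24351494), fell from 21.86 ± 1.69 to 5.48 ± 0.929 CPM (log2 fold change -1.996, SE 0.154, adjusted p 1.28e-11). The other large rises were those of the interferon-induced genes Ifit3 (1.59), Ifit1 (1.33) and Usp18 (1.21), of the matrix genes Ntn4 (1.48) and Col8a1 (1.47), and of Pltp (1.44), Siglecg (1.44), Ahnak2 (1.36) and Ly6a (1.31). The other large falls were those of the Wnt modulators Sfrp2 (-1.64) and Sfrp4 (-1.10), of the preadipocyte genes Dlk1 (-1.58) and Pdgfra (-1.16), of the chemokine gene Cxcl12 (-1.12), and of Plac8 (-1.72), Pi15 (-1.64), H19 (-1.44) and Sned1 (-1.39). Of these, H19 (-1.44), Ifit1 (1.35) and Ifit3 (1.61) were not called in DESeq2 without a replicate term, while the authors' deposited table, which has one, calls Ifit3 (1.57, adjusted p 2.23e-27) and Ifit1 (1.31, adjusted p 1.2e-21) and does not list H19. Plac8 was not called with upper-quartile factors (-1.73), library totals (-1.70) or only the genes of the deposited tables (-1.72), nor Sfrp4 with upper-quartile factors (-1.10), library totals (-1.08) or without stimulated control library 2 (-0.96). Sfrp4 is also not called in the authors' deposited table (-1.09, adjusted p 0.0581). Without the 3 libraries numbered 2, H19, Ifit1, Ifit3, Plac8, Sfrp4, Ly6a (1.33) and Usp18 (1.31) were not called.

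In this comparison 93 genes were higher and 33 lower in the knockdown, of which 32 and 13 changed at least 2-fold. In the fit without a block, an unadjusted p under 0.05 was reached by 1130 of the 29018 genes tested. That is below the share of 0.05 that no effect would give in unpaired libraries. The groups did not overlap for 2824 genes, where chance gives 10% of genes in unpaired libraries, so this count was not above that share. The common dispersion was 0.0165 in this fit and 0.00441 with a replicate block. If equal numbers mark pairs, no effect would give smaller shares than these, so the counts cannot show that the knockdown lacked an effect. The DESeq2 Wald test called 47 higher and 20 lower, the fit without the 3 libraries numbered 2 called 14 and 11, all among the genes called with all libraries, and the fit without knockdown library 2 called 59 higher. Upper-quartile factors gave 52 lower calls and 20 at least 2-fold higher, and the 6 libraries compared alone gave 142 higher. The calls of at least 2-fold ran from 18 higher without stimulated control library 1 to 58 higher and 33 lower without knockdown library 1. With a replicate block 367 genes were higher and 245 lower in edgeR, and 229 and 133 in DESeq2. Not every same-number pair passed the limit set in advance in this comparison. The authors' deposited table, whose values a DESeq2 fit with a replicate term gave again, calls 199 genes higher and 112 lower, and the 113 genes called in both had the same sign.

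Interferon-response genes had positive log2 fold changes in the knockdown in all 22 measured members, with a median of 0.68, and 10 of them rose (20 adjusted over the list alone; camera adjusted p 5.33e-56, adjusted p = 0.0532 with an estimated correlation). Ifit3 rose from 15.64 ± 4.95 to 46.94 ± 17.8 CPM and Ifit1 from 21.82 ± 6.07 to 54.83 ± 20.2 CPM (SD, n = 3). Mx2 (1.19), Ifi44 (1.10), Rsad2 (0.99), Oasl2 (0.98) and Isg15 (0.95) rose as well. The authors' deposited table, with a replicate term, calls 15 of the 19 members it lists higher. The DESeq2 Wald test without that term called 1 member, Usp18, and not Ifit3 (1.61), and 0 members were called by edgeR without the 3 libraries numbered 2, where Ifit3 had a log2 fold change of 1.65. Between 6 and 18 members were called with 1 of the 6 libraries left out, 6 without stimulated control library 1, knockdown library 2 or knockdown library 3, and 18 without knockdown library 1.

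Of 16 p53 targets 3 rose, Zmat3 (0.94), the cyclin gene Ccng1 (0.62) and Eda2r (0.58), and 5 adjusted over the list alone (camera adjusted p 3.51e-09, adjusted p = 0.058 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, had a log2 fold change of -0.03 with an adjusted p of 1. Eda2r was not called in DESeq2 without a replicate term (0.59), with DESeq2 size factors (0.58), without the 3 libraries numbered 2 (0.54), or without stimulated control library 1 (0.51) or 2 (0.56) or knockdown library 2 (0.55) or 3 (0.48). Ccng1 was not called without any 1 stimulated control library (0.64, 0.59 and 0.64 without 1, 2 and 3) or without knockdown library 2 (0.63) or 3 (0.55), nor with DESeq2 size factors (0.63), without a filter (0.63) or without the 3 libraries numbered 2 (0.60). The authors' deposited table calls Zmat3 (0.94, adjusted p 3.18e-12), Ccng1 (0.63, adjusted p 4.42e-05) and Eda2r (0.58, adjusted p 8.24e-05) higher. Among 8 nuclear-retained RNA genes Rian fell (-0.99), and 2, Rian and Meg3 (-0.62), fell adjusted over the list alone (camera adjusted p 2.67e-05, adjusted p = 0.0532 with an estimated correlation).

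Preadipocyte and fibroblast markers changed in both directions, with 5 of 19 higher and 2 lower (6 and 4 adjusted over the list alone), and the list was not called (adjusted p 0.193; median -0.02, mean 0.05, test upward). Pdgfra, the platelet-derived growth factor receptor gene, fell from 57.4 ± 5.93 to 25.61 ± 1.27 CPM, and Dlk1 fell from 10.04 ± 1.97 to 3.34 ± 0.037 CPM (SD, n = 3). The smooth muscle actin gene Acta2 rose from 96.17 ± 5.45 to 189.1 ± 23 CPM, and Ly6a (1.31), Col1a1 (0.75), Col1a2 (0.54) and Cd44 (0.53) rose. The DESeq2 Wald test called 3 higher (Acta2, Ly6a and Col1a1) and 2 lower (Pdgfra and Dlk1), and the list was called upward without knockdown library 1 (mean against all genes 0.082).

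Several metabolic lists had small negative medians in the knockdown, while sterol synthesis had a median of 0.03. Of 20 glucose uptake and glycolysis genes Hk2 fell (-0.60, adjusted p 0.0247), also adjusted over the list alone (camera adjusted p 4.63e-04, adjusted p = 0.669 with an estimated correlation). The Hk2 call was lost in DESeq2 without a replicate term (-0.60), with DESeq2 size factors (-0.60), without the 3 libraries numbered 2 (-0.58), without stimulated control library 1 (-0.58) or 3 (-0.54), and without knockdown library 1 (-0.61) or 2 (-0.50). The authors' deposited table calls Hk2 lower (-0.60, adjusted p 3.81e-15). All 18 genes of fatty acid and triglyceride synthesis had negative log2 fold changes with a median of -0.20, and edgeR and DESeq2 called 0 of them, with the same 2, Acacb (-0.41) and Thrsp (-0.41), lower at an unadjusted p under 0.05 and adjusted over the list alone (camera adjusted p 1.62e-07, adjusted p = 0.467 with an estimated correlation). All 25 oxidative phosphorylation genes were negative with a median of -0.14, and in edgeR 0 reached an unadjusted p under 0.05, while DESeq2 called 0 (camera adjusted p 1.93e-05, adjusted p = 0.669 with an estimated correlation). The thermogenic programme had a median of -0.21 with 3 members lower at an unadjusted p under 0.05 (camera adjusted p 4.63e-04, adjusted p = 0.0532 with an estimated correlation). Left-out libraries ended the call of glycolysis (mean against all genes -0.026) and of oxidative phosphorylation (-0.045), both without knockdown library 2, of triglyceride synthesis without stimulated control library 1 (-0.06), and of the thermogenic programme without stimulated control library 3 (-0.034). Ucp1 was 2016 ± 543 CPM in the knockdown against 2447 ± 575 CPM in the stimulated control, a log2 fold change of -0.28 with an SE of 0.174 and an adjusted p of 1. The authors' deposited table calls Ucp1 lower in the knockdown (-0.28, adjusted p 4.74e-04), as well as 5 of 18 triglyceride synthesis, 4 of 20 thermogenic, 2 of 20 glycolysis and 0 of 25 oxidative phosphorylation genes it lists.

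Camera also called, downward, cAMP early response genes (adjusted p 9.96e-04, 0.669 with an estimated correlation), fatty acid uptake and oxidation (0.001, 0.669), adipocyte identity (0.00127, 0.669), lipolysis and lipid droplet (0.00611, 0.669) and H2A.Z deposition and removal (0.0357, 0.748). At an unadjusted p under 0.05 these lists had 3, 1, 1, 1 and 1 lower members. In these lists and in the thermogenic programme, edgeR called 0 members adjusted over all genes or adjusted over the list alone, and DESeq2 called 0. Without knockdown library 2 their means against all genes were -0.015, -0.013, -0.012, 0 and -0.012, and camera called none of them. Without stimulated control library 3 the means were 0.002 for cAMP early response, 0.004 for fatty acid oxidation, 0.034 for lipolysis and -0.028 for H2A.Z deposition genes, and these were not called. The same held without stimulated control library 1 for adipocyte identity (-0.04) and H2A.Z deposition (-0.059), and without knockdown library 1 for fatty acid oxidation (-0.036), lipolysis (-0.068) and H2A.Z deposition (-0.045). The log2 fold changes of Nr4a1, Ppargc1a and Dio2 were -0.24, -0.25 and -0.27, and those of Pparg, Adipoq and Fasn were -0.13, -0.03 and -0.26, each with an adjusted p of 1. The authors' deposited table calls Ppargc1a (-0.24, adjusted p 0.0185) and Fasn (-0.24, adjusted p 0.0163) lower, as well as 2 of 21 fatty acid oxidation and 1 of 16 adipocyte identity genes it lists.

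Lists not called in the knockdown were sterol synthesis (adjusted p 0.118), secreted factors (0.117), the unfolded protein and integrated stress response (0.0705), clock genes (0.172), chromatin looping factors (0.172), mitochondrially encoded mRNA (0.455), other histone variants (0.967), proliferation (0.901), and macrophage (0.631), endothelial (0.827) and skeletal muscle markers (0.631). In these lists the authors' deposited table calls 2 secreted factors and 1 stress response gene lower and 1 sterol synthesis gene higher, while edgeR and DESeq2 without a replicate term called 0 members. In edgeR 1 secreted factor, Hgf (-0.57), fell adjusted over the list alone, and at an unadjusted p under 0.05 the stress response had 4 lower members and no other of these lists more than 1. With 1 library left out some were called, namely the stress response without stimulated control library 1 (mean against all genes -0.118) or 2 (-0.225) or knockdown library 3 (-0.235), and secreted factors without stimulated control library 2 (-0.147) or knockdown library 3 (-0.128). Looping factors were called without stimulated control library 2 (-0.222) or knockdown library 3 (-0.147), clock genes without stimulated control library 2 (-0.222), and sterol synthesis, upward, without stimulated control library 1 (0.166) or knockdown library 3 (0.036). Median, mean and test differed in sign for macrophage (median -0.03, mean 0.13, test upward), proliferation (median -0.005, mean 0.008, test upward) and muscle genes (median -0.007, mean 0.017, test downward).

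Stimulated knockdown and vehicle control differ in both shRNA and stimulation, and this comparison cannot separate them. Glycolysis genes (17 of 20 higher, 2 lower; camera adjusted p 1.31e-58, adjusted p = 0.0327 with an estimated correlation) and cAMP early response genes (21 of 29 higher, 1 lower; 6.79e-46, adjusted p = 0.0453 with an estimated correlation) rose. Ucp1 had a log2 fold change of 5.29 with an SE of 0.211. Interferon-response genes had a median of 0.75 with 15 of 22 higher (18 adjusted over the list alone; camera adjusted p 4.56e-12, adjusted p = 0.391 with an estimated correlation), and DESeq2 called 5 (Ifit1, Oas1a, Irf9, Mx2 and Usp18). In all, 1460 genes were higher and 1692 lower. Upper-quartile factors gave 2819 higher calls, library totals 3222 lower calls and the DESeq2 Wald test 842 lower calls. A replicate block gave 2715 higher and 3325 lower. The share that were higher was 46.3% with TMM, 56.7% with DESeq2 size factors, 61.9% with upper-quartile factors and 34.4% with library totals, and the lower calls ran from 851 without vehicle library 3 to 2256 without vehicle library 2.

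The last question was whether genes induced by CL316,243 were lower in the knockdown. Of the 1401 induced genes 3 were called lower in the knockdown, Hk2, Slc4a4 and Rrp12, where 1.59 would be shared by independent lists. The lists are not independent, since both comparisons use the stimulated control libraries. Slc4a4, a sodium bicarbonate cotransporter gene, rose with CL316,243 by a log2 fold change of 2.02 and fell in the knockdown (-0.74, adjusted p 0.00327), and Rrp12, a ribosome biogenesis gene, rose by 1.09 and fell (-0.59, adjusted p 0.0221). The overlap was 0 in the DESeq2 Wald test and without the 3 libraries numbered 2, 0 to 6 with 1 library left out, 1 with DESeq2 size factors, 5 with library totals, 8 with only the genes of the deposited tables and 11 with upper-quartile factors. It was 77 with a replicate block and 38 with the block in DESeq2. Of genes lower with CL316,243, 6 were higher in the knockdown, where 4.53 would be shared by independent lists, while 4 genes were higher in both (Cd44, Cdk18, Col12a1 and Kcnj15) and Gas1 was lower in both, named here after their values were seen. The overlap of 6 became 0 without the 3 libraries numbered 2, 2 in the DESeq2 Wald test, 3 to 15 with 1 library left out, 10 without a filter or with a CPM of at least 1 in 3 libraries, 12 with upper-quartile factors, 20 with only the genes of the deposited tables and 34 with library totals. It was 84 with a replicate block and 34 with the block in DESeq2. In simulations of unpaired libraries with the CL316,243 effect alone, the overlap of induced genes lower in the knockdown averaged 0.04 (0 to 1). That of repressed genes higher in the knockdown averaged 0.2 (0 to 2). Those simulations held no knockdown effect and averaged 0.52 calls in the knockdown, so overlaps near 0 follow from their construction.

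Both comparisons use the stimulated control libraries with opposite signs, so their fold changes are negatively correlated with no knockdown effect. Across the 29018 genes, which are not independent replicates, Pearson r was -0.329 (jackknife SE 0.128) and Spearman rho -0.325, against a mean simulated r of -0.315 with the CL316,243 effect alone. The observed r was -0.159 with only the genes of the deposited tables, -0.19 in DESeq2, -0.156 in DESeq2 with the block, -0.486 without a filter and -0.567 without stimulated control library 2. The 416 genes induced at least 2-fold had a median log2 fold change of -0.10 in the knockdown (jackknife SE 0.088), and 319 of them (76.7%) were below 0. In simulated data with the CL316,243 effect alone this median averaged -0.0853 (-0.118 to -0.0643) and the share 65.4% (60.6% to 69%). Of all 1401 induced genes 70.1% were below 0, against 60.3% to 65.6% in these simulations. With simulated libraries paired by replicate number, the median averaged -0.0228 (-0.0348 to -0.00595), r averaged -0.283, and the shares ran from 52.2% to 61.8% and from 54.3% to 60.2%. The median was -0.045 without knockdown library 2 and -0.169 without stimulated control library 2.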

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

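The alternatives without the 3 libraries numbered 2, with the block under a robust prior and with the block in DESeq2 were chosen after seeing the data. Of 77 called named genes with CL316,243, 64 were called under every alternative that tested them, and of 27 in the knockdown, 16 were. An alternative that left a gene untested was not counted against it, and the limit of 0.01 was not applied to single genes here. With 1 library of a group left out the other groups' spread stands in for it. Genes changed 1.5-fold were recovered in 41.8% and 47.8% of cases on simulated unpaired libraries, so the fit without a block often misses changes of that size. These were drawn at the dispersion of that fit, whose common value was 0.0165, against 0.00441 with the replicate block. Recovery by a fit with the block was not simulated. Over the scalings, the median log2 fold change of all genes with CL316,243 ran from -0.157 with library totals to 0.014 with upper-quartile factors, against -0.06 with TMM. It ran from -0.007 to 0.017 in the knockdown, and from -0.123 to 0.026 in stimulated knockdown against vehicle control. Except where a value or the construction of the alternative shows it, the cause was not tested.

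With DESeq2 size factors 859 genes were lower with CL316,243, 1094 were lower in stimulated knockdown than in vehicle control, and 1 CL-induced gene was lower in the knockdown. With upper-quartile factors 2860 genes were higher with CL316,243, 81 at least 2-fold lower, 52 lower in the knockdown, 20 at least 2-fold higher there and 2819 higher in stimulated knockdown than in vehicle control. The overlaps were then 11 CL-induced genes lower and 12 CL-repressed genes higher in the knockdown. Pparg and Adipoq turned to 0.01 and 0.02 with CL316,243, and the looping list to a mean of 0.006 against all genes, from a value that rounds to 0. With library totals 3204 genes were lower with CL316,243, 187 at least 2-fold, and 3222 were lower in stimulated knockdown than in vehicle control. The overlaps were then 5 and 34, H2afz was called with CL316,243 (-0.37), and 3 list means lay at 0 (muscle, CL316,243), 0.004 (looping, CL316,243) and -0.002 (mitochondrially encoded mRNA, knockdown).

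Without a filter 10 CL-repressed genes were higher in the knockdown and the correlation of fold changes was -0.486, among 51076 genes tested. List means turned to -0.011 for muscle and 0.021 for looping with CL316,243, and to -0.176 for mitochondrially encoded mRNA, -0.025 for macrophage and -0.05 for muscle markers in the knockdown. With a CPM of at least 1 in 3 libraries 10 CL-repressed genes were higher in the knockdown. List means turned to -0.063 for mitochondrially encoded mRNA with CL316,243, and to -0.043 for macrophage, -0.095 for muscle and 0.005 for proliferation genes in the knockdown. With only the genes of the deposited tables, 13047 genes, 2154 were higher with CL316,243, 237 at least 2-fold higher and 73 at least 2-fold lower, 21 were at least 2-fold higher in the knockdown, and 2271 were higher in stimulated knockdown than in vehicle control. The overlaps were then 8 and 20 and the correlation -0.159. List means turned to -0.062 for mitochondrially encoded mRNA and -0.072 for muscle markers with CL316,243, and to -0.072 for macrophage, -0.144 for muscle and 0.013 for proliferation genes in the knockdown. At an adjusted p under 0.01, 801 genes were lower with CL316,243, 60 higher and 21 lower in the knockdown, and 1011 lower in stimulated knockdown than in vehicle control, which the stricter limit itself brings.

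The DESeq2 Wald test called 669 genes lower with CL316,243, 47 higher and 20 lower in the knockdown, 21 at least 2-fold higher there, and 842 lower in stimulated knockdown than in vehicle control. The overlaps were 0 and 2 and the correlation -0.19. List means turned to -0.08 for mitochondrially encoded mRNA, -0.056 for muscle and -0.009 for p53 targets with CL316,243, and to -0.039 for macrophage, -0.097 for muscle and 0.006 for proliferation genes in the knockdown. With only the 6 libraries compared 142 genes were higher in the knockdown, and list means there turned to -0.041 for muscle and 0.003 for proliferation genes. With an estimated correlation 3 lists were called with CL316,243 and 0 in the knockdown, against 10 and 12 with the preset one, and with fry 5 and 0. The estimated correlation and fry were used only without the replicate block. There an effect shared by equal numbers, if present, would enter the estimate, so these counts do not cover a paired model. Without the 3 libraries numbered 2, 14 genes were higher and 11 lower in the knockdown, 9 at least 2-fold higher, all 25 being among the genes called with all libraries, and the overlaps were 0 and 0. List means then turned to 0 for mitochondrially encoded mRNA and -0.012 for fibroblast markers with CL316,243, and to 0.082 for endothelial and -0.163 for muscle markers in the knockdown. Fewer libraries did not always bring fewer calls. In the knockdown 185 genes were called without knockdown library 1 and 82 without knockdown library 2, against 126 with all libraries.

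A fit with a replicate block called 2632 genes higher and 3013 lower with CL316,243, 367 and 245 in the knockdown, and 2715 and 3325 in stimulated knockdown against vehicle control, among them every gene called without the block. Its overlaps were 77 and 84. H2afz was called with CL316,243 (-0.27), and list means turned to 0.002 for looping with CL316,243 and to -0.003 for mitochondrially encoded mRNA and -0.005 for muscle in the knockdown. Under a robust prior the counts were 2667 and 3032, 380 and 253, and 2739 and 3323, the overlaps 79 and 89, H2afz was called (-0.27), and the same 3 list means were 0.002, -0.003 and -0.005. The prior degrees of freedom were infinite in both fits, which gives every gene the trend's spread, while 20 genes were spread beyond it. With the block in DESeq2, which estimates a spread per gene, 2571 genes were higher with CL316,243, 81 at least 2-fold lower, 229 higher and 133 lower in the knockdown, and 2636 higher in stimulated knockdown than in vehicle control. The overlaps were then 38 and 34, the correlation -0.156, and H2afz was called with CL316,243 (-0.22). List means turned to -0.073 for mitochondrially encoded mRNA and -0.087 for muscle with CL316,243, and to -0.064 for macrophage, 0.063 for endothelial, -0.142 for muscle, 0 for other histone variants and 0.015 for proliferation genes in the knockdown. The block changed no camera call of a list with CL316,243, and in the knockdown camera called 4 further lists with it, sterol synthesis and fibroblast markers upward and secreted factors and the stress response downward. Ucp1 (-0.29, -0.29 and -0.28) and Fasn (-0.25 in each) were called lower in the knockdown in these 3 fits with the block, and Ppargc1a (-0.25) in the first of them. Same-number correlations were 0.05, 0.31 and 0.25 between knockdown and stimulated control and 0.06, 0.33 and 0.33 between knockdown and vehicle control. Not every pair thus passed the limit of 0.1 set in advance, although the authors' table pairs equal numbers between knockdown and stimulated control. Stimulated control library 1 and vehicle library 1 each correlated best with knockdown library 3 (0.14 and 0.08). By chi-square per degree of freedom, however, each stimulated control library lay closest to the knockdown library of its own number (4, 3.6 and 4.48). Stimulated control libraries 1 and 2 were about equally close to knockdown library 1 (4 and 4.01). Vehicle library 3 lay closer to knockdown libraries 1 (31.7) and 2 (28.2) than to knockdown library 3 (34.65).

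With 1 library left out, genes higher with CL316,243 ran from 907 to 1382, lower from 683 to 1938, at least 2-fold higher from 355 to 459 and at least 2-fold lower from 77 to 176. In the knockdown the ranges were 59 to 138 higher, 23 to 47 lower, 18 to 58 at least 2-fold higher and 12 to 33 at least 2-fold lower. Against vehicle control they were 1004 to 1538 higher and 851 to 2256 lower. The overlaps ran from 0 to 6 and from 3 to 15, the correlation from -0.567 to -0.25, the median of induced genes from -0.169 to -0.045, and the lists called from 9 to 13 with CL316,243 and from 5 to 16 in the knockdown. H2afz ran from -0.34 to -0.17 with CL316,243 and from -1.18 to -0.97 in the knockdown, and H2afv from -0.83 to -0.49 and from 0 to 0.17.

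Uncalled named genes changed sign with 1 library left out. With CL316,243 Pparg ran from -0.21 to 0.02 and Adipoq from -0.13 to 0.04, and in the knockdown Pparg from -0.22 to 0.02, Adipoq from -0.11 to 0.04, Nr4a1 from -0.47 to 0.04 and Ppargc1a from -0.57 to 0.07. List means against all genes with CL316,243 ran from -0.109 to 0.188 (adipocyte identity), -0.162 to 0.158 (looping), -0.06 to 0.244 (triglyceride synthesis), -0.057 to 0.23 (H2A.Z deposition), -0.222 to 0.183 (interferon), -0.02 to 0.341 (mitochondrially encoded mRNA), -0.248 to 0.071 (other histone variants), -0.087 to 0.102 (p53 targets), -0.013 to 0.083 (fibroblast) and -0.085 to 0.163 (muscle). In the knockdown they ran from -0.306 to 0.002 (cAMP early response), -0.222 to 0.021 (looping), -0.136 to 0.06 (endothelial), -0.286 to 0.004 (fatty acid oxidation), -0.286 to 0.034 (lipolysis), -0.156 to 0.096 (mitochondrially encoded mRNA), -0.174 to 0.098 (other histone variants), -0.153 to 0.097 (proliferation), -0.147 to 0.104 (muscle), -0.084 to 0.166 (sterol synthesis) and -0.235 to 0.042 (stress response).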

Other observations

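Further targets of hypoxia-inducible factors rose with CL316,243 in control cells. After Egln3, Slc2a1 and Vegfa had been seen to rise, 27 further target genes not yet looked at were listed, of which 19 rose and 1 fell (20 and 2 adjusted over the list alone), with a median log2 fold change of 0.995 (camera p 3.09e-39, p = 0.00199 with an estimated correlation of 0.269). Ankrd37 rose by 2.3, the prolyl hydroxylase gene Egln1 by 1.55, and the mitophagy receptor gene Bnip3 by 1.31, with SE of 0.186, 0.151 and 0.147 over 3 libraries per group. The glycogen synthase gene Gys1 (1.31) and the demethylase gene Kdm4b (1.28) rose too, while the transferrin receptor gene Tfrc fell (-1.3). These data are consistent with a wider rise of such targets, which is a hypothesis, since the list was drawn up after other members had been seen.

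The tests of low control values, of adipocyte share and of sequencing depth below were chosen only after the result was seen. The interferon-response genes had a median log2 fold change of 0.68 in the knockdown. A single library is argued against as the whole cause of this median, since it stayed at 0.562 or above with any 1 of the 6 libraries left out, and low values in the stimulated control are too, since the median was 0.75 against the vehicle control. A difference between the shRNA viruses other than H2A.Z loss cannot be told apart from H2A.Z loss, because the labels give 1 group with an H2A.Z shRNA. An effect of H2A.Z loss stays open and untested against it. The number of members called depended on the model, at 1 in DESeq2 without a replicate term and 15 of 19 in the authors' deposited table, which has that term.

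Genes induced at least 2-fold by CL316,243 had a median log2 fold change of -0.098 in the knockdown. A lower share of adipocytes in the knockdown cultures stays open. Fibroblast markers did not rise together, being called in both directions, down to -1.58 for Dlk1. This cannot decide the question, since 16 of 17 adipocyte identity genes had negative log2 fold changes (median -0.13), which a lower share could also give. The shared stimulated control libraries may account for part of the negative median of the induced genes. Of 50 simulated data sets of unpaired libraries with no knockdown effect, 5 had a median as low, but 0 of 50 did with libraries paired by replicate number. The shares below 0, 76.7% of these genes and 70.1% of all induced genes, lay above every draw of both simulations. A knockdown effect on these genes stays open, and the median was -0.045 without knockdown library 2.

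The libraries numbered 2 had the lowest value on the first principal component in each group. Lower sequencing depth is argued against, since they had at least 761 more genes with 10 or more counts than the other libraries of their group. Reads spread over genes silent in adipocytes are a candidate explanation, since 1780 olfactory, vomeronasal and taste receptor genes took a share of counts at least 1.41 times the mean of the other libraries in each group. They took 1880, 1670 and 1530 CPM of raw totals in the libraries numbered 2 and 846 to 1260 in the others. No biological explanation was tested, and a shared day or culture of equal numbers is not given by the labels.

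Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many calls. The real split gave 2814 calls for stimulated against vehicle control and the highest other split 0, among them the 3 others that part every same-number pair. For stimulated knockdown against stimulated control these values were 126 and 60, the latter from the split of stimulated control libraries 1 and 2 and knockdown library 1 against the rest. The other splits there that part every same-number pair gave 0. For stimulated knockdown against vehicle control the real split gave 3152 calls and the highest other split 0.

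After H19, Dlk1 and Rian had been seen to fall in the knockdown, 20 further imprinted genes were tested, with a median log2 fold change of 0.012 and a camera p of 0.638. This argues against a fall shared by these 20 genes. Genes already seen or in a fixed list were left out of them, so a fall limited to some imprinted loci was not tested. After Acta2, Col1a1 and Col8a1 had been seen to rise, 20 further contractile and matrix genes had a median of 0.138 with 1 higher, Col5a1 (0.51), and 1 lower, Lox (-0.57), or 7 higher and 2 lower adjusted over the list alone. Their camera p was 5.63e-04, and p = 0.103 with an estimated correlation, which leaves a wider rise undecided.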
